A study of Mus musculus with 4 samples.

How the data were processed

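RNA was measured by sequencing of mRNA libraries made with an Illumina TruSeq protocol, in 2 libraries of CD301b macrophages and 2 libraries of F4/80-negative immune cells sorted from day 5 mouse wound beds, per the labels' protocols. The series design states that cells were isolated by sorting, and the replicate numbers in the labels were not used to pair libraries. The submitters' processing notes name TopHat2 2.0.2, Cuffdiff 2.0.2 and the genome build mm9. The counting settings, including strand, are not given in the sources used here, so reads of overlapping antisense genes may not be told apart, and the same holds for close copies such as Ly6c1 and Ly6c2.

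The authors deposited 1 table of the whole series with 34535 transcripts, named by RefSeq accession and gene symbol. Per the file headers it gives, for each transcript, 1 FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) for each population, a log2 fold change, an unadjusted p-value, a test status and a call of significance. How the libraries of a population were combined into its FPKM is not given in the sources used here. The p-value was deposited by the authors with a lower limit of 5e-05, shared by 847 transcripts. The status was OK for 16921 transcripts, NOTEST for 17610 and FAIL for 4. The deposited calls matched a Benjamini-Hochberg adjustment at 0.05 over the OK transcripts in every transcript (2408 calls, largest unadjusted p 0.0071). That adjustment is what "adjusted p" means throughout. The deposited log2 fold held a spreadsheet error in 1788 cells and was not used. The FPKM ratio recomputed from the 2 columns differed from it by at most 1.26e-05 above 1 FPKM. Symbols that a spreadsheet had turned into dates (25 symbols, 56 transcripts) were replaced through their accession.

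The coordinates in the table were compared with RefSeq genes of GRCm38.p6. Of the accessions, 98.9% were found there, and 98.0% of these had a locus overlapping that gene, so the table's coordinates are those of GRCm38 and not of mm9. The loci start 1 base before the RefSeq gene in 17342 cases, which is the 0-based convention. Positions printed are RefSeq gene positions on GRCm38, counted from 1.

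The table holds no read counts. FPKM times transcript length showed no steps in single-transcript genes (13013 distinct values among 13044 in F4/80-negative cells), so whole reads and the depth of each library could not be recovered, and no counting interval is given. With no values per library, no test of differences was run here. Significance rests on the authors' deposited p-values, and no test of gene lists across libraries was possible.

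Transcripts were gathered by gene symbol and their FPKM summed. A gene was called higher (or lower) when at least 1 transcript passed an adjusted p of 0.05 in that direction, none passed in the other and the summed FPKM went the same way. By this rule 13 genes had transcripts in both directions and 26 had a passing transcript against the sum, and neither kind was counted as higher or lower. Ratios are of summed FPKM. The adjusted p given for a gene is the smallest among its tested transcripts. In a gene with several transcripts it is therefore not a test of the summed FPKM. Log2 folds are on the log2(FPKM + 1) scale, which understates the change of low genes. The analysis used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

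Before the data were examined, 26 gene lists, the design, the alternatives and the rule for named genes were fixed. The lists cover genes of sort and gate markers (Adgre1, Mgl2, Ptprc and Itgam, of which the labels name F4/80 and CD301b alone), macrophage core, alternatively activated and inflammatory macrophage genes, growth factors, chemokines, matrix turnover, lysosome and lipid handling, phagocytosis and complement, iron and haem handling, interferon response, glycolysis and hypoxia, cell cycle, MHC class II, and markers of neutrophils, T cells, gamma delta T and innate lymphoid cells, natural killer cells, B cells, dendritic cells, mast cells with basophils and eosinophils, fibroblasts, keratinocytes, endothelium, platelets with erythroid cells, and muscle with adipocytes. Some genes stand in several lists. Each list is described by its calls, by the calls when the p-values were adjusted over the list alone, and by the percentile of its median log2 fold among 10000 random lists matched on mean expression (each member replaced by one of about 200 genes of neighbouring expression). Genes are not independent replicates, so the percentile describes these libraries only. Named genes were Adgre1, Mgl2, Ptprc and Itgam, the 12 genes with the largest log2 fold in each direction among called genes at 10 FPKM or more (predicted and receptor segment genes left out), up to 4 called members of each list at 5 FPKM or more, or its most abundant members where there was none, all growth factors, the 3 highest genes of each population and the 4 most abundant genes with opposite transcripts. Other list members named beside these were chosen after their values were seen, to complete a count or to show a member's level. Single values of some list members are not reported here.

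The steps were tested on simulated data for this comparison with 13039 tested genes. With a simulated error of 0.3 on the log2 scale per transcript, 100% of 100 genes changed by a log2 fold of 2 and 45.0% of 100 genes changed by a log2 fold of 1 were called, none in the wrong direction, and 0.0935% of unchanged genes were called. The simulated p-values were computed with the same error that was drawn, independently for each transcript. These shares therefore check the calling steps and do not give the error rate of the authors' Cuffdiff p-values. Of 100 simulated lists of 15 unchanged genes, 3 fell outside the central 95% of random lists, and of 100 shifted by 0.5, 100 did. Members of the simulated lists varied independently, so these shares do not give the error rate of the percentiles of the real lists. Alternatives tried were a stricter threshold, Bonferroni adjustment, minimum FPKM values, a minimum fold, other ways to combine transcripts, other pseudocounts and rescaling of the populations.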

Results

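The transcriptomes of 2 cell populations sorted from the dermis of mouse wound beds on day 5 were compared. One was CD301b-positive macrophages, a wound macrophage subset that bears the C-type lectin CD301b. The other was immune cells negative for F4/80, the surface protein most widely used to mark mouse macrophages. Cells came from 7-week-old male C57/Bl6 mice and were isolated by fluorescence-activated cell sorting, and each population was represented by 2 libraries. The comparison asked which transcripts distinguish CD301b macrophages from F4/80-negative immune cells of the wound at this time. No library of wound macrophages without CD301b was included. Traits of the CD301b subset therefore cannot be told apart from traits of wound macrophages in general. Expression was available as 1 FPKM value per transcript and population, so the spread between the libraries of a population could not be computed, and no error accompanies any FPKM given here. Where a pair of values is written as A against B, the first is CD301b macrophages and the second F4/80-negative cells. Counts of reads were not given, so the depth of each library is unknown. It is not stated whether the libraries came from separate animals, nor how the spread between libraries entered the p-values. The p-values therefore cannot be read as covering the spread between animals. The highest-expressed genes were Fth1, ferritin heavy chain, in both populations (9449 FPKM in F4/80-negative cells and 11003 FPKM in CD301b macrophages), Tmsb4x, an actin-binding thymosin, in F4/80-negative cells (7484 FPKM), Lyz2, the myeloid lysozyme, in CD301b macrophages (9621 FPKM) and Ftl1, ferritin light chain, in both (6006 and 8083 FPKM).

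Macrophage core genes were higher in CD301b macrophages in 15 of 18 cases and lower in none, and dendritic and Langerhans cell markers were lower in 10 of 15 cases and higher in none. Among the 13039 genes with a tested transcript, 1432 were higher and 808 were lower in CD301b macrophages at an adjusted p of at most 0.05 (Benjamini-Hochberg adjustment of the Cuffdiff p-values in the authors' deposited table). Of these genes, 287 were at least 2-fold higher and 189 at least 2-fold lower on the log2(FPKM + 1) scale. Ednrb, the endothelin B receptor, was 6.34-fold higher (82.4 against 12.99 FPKM) and Gpr34, a lysophospholipid receptor, was 6.20-fold higher (43.0 against 6.93 FPKM). Sepp1, the secreted selenium carrier selenoprotein P, was 4.87-fold higher and reached 3362 FPKM. Cd300lh, of the CD300 receptor family, was 5.10-fold higher, and Folr2, the folate receptor beta of tissue macrophages, was 4.64-fold higher. Cd163, the haemoglobin scavenger receptor, and Stab1, the scavenger receptor stabilin-1, were 4.89-fold and 4.50-fold higher. Maf, a transcription factor of resident macrophages, was 4.77-fold higher. The remaining genes among the 12 with the largest rise were Nxpe5 (5.01-fold), Wwp1 (4.81-fold), Cbr2 (4.78-fold) and Npl (4.65-fold). In the other direction, Klrd1, which encodes the lectin-like receptor CD94, was 8.86-fold higher in F4/80-negative cells (4.18 against 37.1 FPKM). Ccr7, the receptor that guides migrating dendritic cells, was 7.56-fold higher there, and the chemokines Ccl17 and Ccl22 were 7.66-fold and 6.47-fold higher. Ctsk, the collagen-degrading protease cathepsin K, was 443 FPKM in F4/80-negative cells and 79.8 FPKM in CD301b macrophages, a 5.56-fold difference. Slc9b2 (7.63-fold), Flt3 (6.36-fold), Il4i1 (6.18-fold), H2-Oa (6.11-fold), Ramp3 (6.02-fold), P2ry10 (5.91-fold) and AA467197 (4.97-fold) completed the 12 genes with the largest fall. Each of these 24 genes had an adjusted p of 0.000999, which is the smallest value that the p-values in the authors' deposited table allow.

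**Figure D1:**
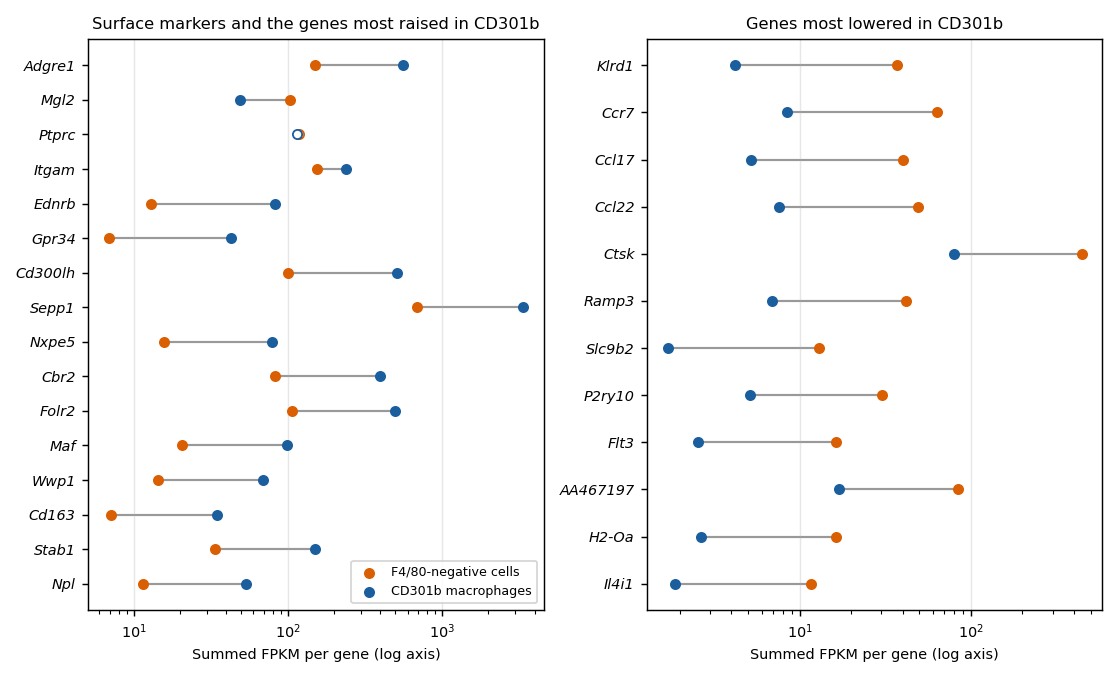
Summed FPKM per gene (log axis) in F4/80-negative cells (orange) and CD301b macrophages (blue), with 1 value per population and no error bars. Open circles mark a gene not past the threshold. On the left are the 4 surface marker genes Adgre1, Mgl2, Ptprc and Itgam and the 12 genes with the largest rise, led by Ednrb at 6.34-fold, and on the right the 12 with the largest fall, led by Klrd1 at 8.86-fold. Mgl2 is the only one of these 4 past the threshold that is lower in CD301b macrophages.

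The transcripts of F4/80 and CD301b, the surface proteins that name the populations, did not both follow the sort. Adgre1, which encodes F4/80 (NCBI gene 13733, chromosome 17, 57358581 to 57483529, GRCm38), was 3.69-fold higher in CD301b macrophages, at 557 against 151 FPKM. The Adgre1 level in F4/80-negative cells was 27.1% of that in the macrophages. The sources used here do not say whether CD45 or CD11b served in the sort. Of the 4 genes of F4/80, CD301b, CD45 and CD11b, 2 were higher, 1 was lower and 1 was not past the threshold, with the same higher and lower counts when adjusted over the list alone and a median log2 fold of 0.30 (percentile 78.1 of matched random lists). Mgl2, which encodes CD301b (NCBI gene 216864, chromosome 11, 70130125 to 70137542), went the other way and was 2.09-fold lower in CD301b macrophages, at 49.2 against 103 FPKM. Both had an adjusted p of 0.000999 from the authors' deposited table. Itgam, which encodes the myeloid integrin CD11b, was 1.56-fold higher in CD301b macrophages. Ptprc, which encodes the leukocyte marker CD45, was 118 FPKM in F4/80-negative cells and 116 FPKM in CD301b macrophages and was not past the threshold. Mgl2 shares part of its sequence with its neighbour Clec10a: 15.7% of the 50-base words in its transcript also occur in Clec10a, and reads from those parts cannot be assigned with certainty. Clec10a itself was 1.57-fold higher in CD301b macrophages.

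Macrophage genes were higher in CD301b macrophages as a group. Of 18 macrophage core genes, 15 were higher, none was lower and 3 were not past the threshold (15 higher when adjusted over the list alone), with a median log2 fold of 1.22. That median lay at percentile 100 of 10000 random lists matched on mean expression, and percentiles of the other lists are given in the same way. C1qa, a subunit of the complement component C1q, was 3.60-fold higher at 1530 FPKM, and Gas6, a ligand of the efferocytosis receptor Mertk, was 3.40-fold higher. Genes of phagocytosis and complement behaved alike: 14 of 20 were higher and 2 were lower, with the same counts when adjusted over the list alone and a median log2 fold of 1.0 (percentile 100). The members behind these counts differed. Adjusted over the list alone, Marco (0.906 against 0.354 FPKM) became higher, and Fcgr2b, higher before, had transcripts past the threshold in both directions. C1qb and C1qc were 3.33-fold and 3.08-fold higher. The 2 lower members were Itgax, which encodes the dendritic cell integrin CD11c and was 2.67-fold lower, and Timd4, at 0.346 against 1.41 FPKM. Among the core genes, Cd14 (457 against 518 FPKM), Axl (52.3 against 51.5 FPKM) and Cd63 (616 against 494 FPKM) were not past the threshold.

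Genes listed under alternative macrophage activation split between the populations. Of 18, 11 were higher in CD301b macrophages, 5 were lower and 2 were not past the threshold, with the same counts when adjusted over the list alone and a median log2 fold of 0.73 (percentile 100). Folr2, Cd163, Stab1 and Lyve1, a hyaluronan receptor of perivascular macrophages (5.33-fold), had the largest folds among the higher members. Besides Mgl2, the lower members were Chil3 (21.8 against 55.4 FPKM), Retnla (167 against 274 FPKM), Cd209d (14.5 against 29.0 FPKM) and Pdcd1lg2 (1.36 against 3.27 FPKM). Of 14 tested inflammatory macrophage genes, 4 were lower, 2 were higher and 8 were not past the threshold, and 3 were higher and 4 lower when adjusted over the list alone. Their median log2 fold was -0.02 (percentile 24.9). Il6 was 2.80-fold lower, Il1b, at 761 against 1178 FPKM, was 1.55-fold lower, and Cd38, an NAD-consuming ectoenzyme, was 3.51-fold higher in CD301b macrophages. The other higher member was Tnf, at 53.7 against 36.5 FPKM (adjusted p = 0.0456, from the Cuffdiff p-values of the authors' deposited table). Ly6c2, a marker of recently arrived monocytes, was 2.85-fold lower, with the reservation that it is a close copy of Ly6c1. Nos2 was 9.92 against 8.37 FPKM and was not past the threshold.

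Of 24 tested secreted growth factors, 4 were higher in CD301b macrophages and 2 were lower. Pdgfc, which encodes platelet-derived growth factor C, a mitogen for fibroblasts, was 3.64-fold higher (24.0 against 6.60 FPKM), and Igf1, insulin-like growth factor 1, was 2.77-fold higher (36.8 against 13.3 FPKM). Grn, which encodes progranulin, was 2.47-fold higher at 954 FPKM, and Bmp2 was 3.03-fold higher at 5.04 FPKM. Lif (4.61 against 7.09 FPKM, adjusted p = 0.0346) and Tgfb2 (1.64 against 2.61 FPKM, adjusted p = 0.0469) were lower, from the Cuffdiff p-values of the authors' deposited table. The other 18 tested growth factors were not past the threshold, among them Pdgfa (10.9 against 10.7 FPKM), Pdgfb (13.01 against 15.95 FPKM), Vegfa (48.3 against 59.4 FPKM) and Osm (109 against 103 FPKM). Tgfb1, at 105 against 74.4 FPKM, had an adjusted p of 0.0779, from the same Cuffdiff p-values of the authors' deposited table. Adjusted over the list alone, 5 growth factors were higher and 4 lower. The list's median log2 fold was -0.24, at percentile 0.1 of matched random lists, while its mean was 0.06, so the median and the mean had opposite signs.

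**Figure D2:**
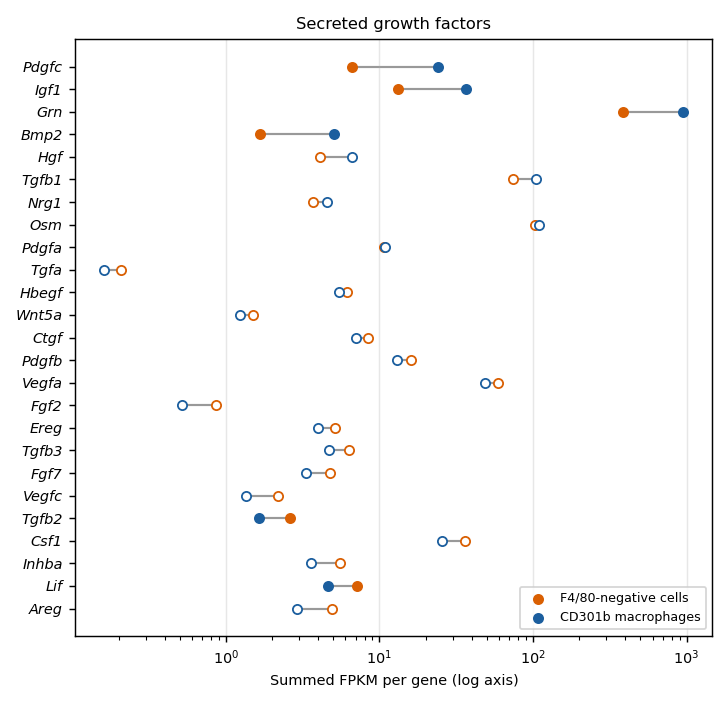
Summed FPKM per gene (log axis) for the 25 secreted growth factors in F4/80-negative cells (orange) and CD301b macrophages (blue), ordered by fold, with 1 value per population and no error bars. Filled circles mark the 6 genes past the threshold: Pdgfc, Igf1, Grn and Bmp2 are higher in CD301b macrophages, and Tgfb2 and Lif are lower.

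Chemokines divided evenly. Of 23, 5 were higher, 5 were lower and 13 were not past the threshold, and 9 were higher and 5 lower when adjusted over the list alone. Ccl8, a monocyte attractant, was 3.91-fold higher at 1924 FPKM in CD301b macrophages, and Ccl12 was 3.11-fold higher. Ccl17 and Ccl22, ligands of the chemokine receptor CCR4, had the largest folds among the lower members. The list's median log2 fold was 0.11 (percentile 67.4) and became 0.0002 when each population was scaled to its median gene, so no direction is given for the list as a whole. Extracellular matrix turnover genes were more often lower: 7 of 23 were lower, 3 were higher and 12 were not past the threshold, with 10 lower and 4 higher when adjusted over the list alone. In 1 gene of this list, Adam17, the transcript past the threshold went against the summed FPKM. Their median log2 fold was -0.27 (percentile 0.07). Besides Ctsk, the elastase Mmp12 was 3.85-fold lower and the gelatinase Mmp9 was 2.84-fold lower, whereas Ctsb, a lysosomal protease, was 2.88-fold higher at 1765 FPKM. Fibroblast markers moved in the same direction as this list, with a median log2 fold of -0.45.

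Genes of lysosomes and lipid handling were higher in CD301b macrophages in 12 of 23 cases and lower in 1, with a median log2 fold of 0.69 (percentile 100; 14 higher and 1 lower when adjusted over the list alone). Apoe, the lipid carrier apolipoprotein E, was 3.21-fold higher at 7115 FPKM. Abca1, a cholesterol exporter, was 2.28-fold higher, Ctsd 2.24-fold and Lamp1 2.20-fold. The lower member was Fabp4, a fatty acid carrier, at 81.1 against 128 FPKM. Of 11 genes of iron and haem handling, 5 were higher, 1 was lower and 5 were not past the threshold, with a median log2 fold of 0.60 (percentile 99.8; 6 higher and 1 lower when adjusted over the list alone). Slc40a1, the iron exporter ferroportin, was 3.38-fold higher, Trf, transferrin, 3.08-fold, and Hmox1, haem oxygenase 1, 2.41-fold. Of 14 interferon response genes, 9 were higher, 1 was lower and 4 were not past the threshold, with the same counts when adjusted over the list alone and a median log2 fold of 0.58 (percentile 99.99). Ifit2 (2.32-fold), Ifit3 (2.15-fold) and Ifit1 (1.79-fold) were among the higher members, and Isg15 was lower at 65.9 against 102 FPKM.

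Glycolysis and hypoxia genes showed 1 change among 15, with the same count when adjusted over the list alone. Ldha, lactate dehydrogenase A, was 1.36-fold higher in CD301b macrophages by summed FPKM. Its call rested on a noncoding transcript (93.3 against 42.3 FPKM). The main coding transcript of Ldha (422 against 337 FPKM) was not past the threshold. The list's median log2 fold of 0.11 (percentile 62.05) became -0.003 under median scaling. None of 17 cell cycle genes was past the threshold, also when adjusted over the list alone, and their median log2 fold was -0.12 (percentile 4.24). Pcna, the DNA polymerase clamp, was 98.0 FPKM in F4/80-negative cells and 99.0 FPKM in CD301b macrophages, and Mcm6 was 22.2 and 23.7 FPKM.

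Dendritic cell genes were lower in CD301b macrophages. Of 15 dendritic and Langerhans cell markers, 10 were lower and none was higher (11 lower when adjusted over the list alone), with a median log2 fold of -0.95. Besides Ccr7 and Flt3, the receptor that sustains dendritic cell development, Cd209a was 4.15-fold lower and Itgax 2.67-fold lower. Of 8 genes of antigen presentation by MHC class II, 7 were lower and none was higher, also when adjusted over the list alone, with a median log2 fold of -0.86. H2-Oa was 6.11-fold lower, while the abundant H2-Ab1 and H2-Eb1 were 2.01-fold and 1.97-fold lower and stayed at 1676 and 799 FPKM. Mast cell, basophil and eosinophil markers were lower in 8 of 13 tested cases and higher in none (11 lower when adjusted over the list alone), with a median log2 fold of -0.60. Kit was 5.03-fold lower, and the mast cell proteases Mcpt4, Cpa3 and Cma1 were 2.86-fold, 2.81-fold and 2.58-fold lower. All 3 medians lay at percentile 0 of matched random lists.

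Neutrophil and lymphocyte markers gave a mixed picture. Of 17 tested neutrophil markers, 5 were lower in CD301b macrophages, 2 were higher and 10 were not past the threshold (6 lower and 2 higher when adjusted over the list alone). The alarmins S100a8 and S100a9 were 1.84-fold and 1.85-fold lower, Il1r2, the interleukin 1 decoy receptor, was 99.3 against 249 FPKM and lower, and Cxcr2 was 27.3 against 25.7 FPKM, not past the threshold. Csf3r, also counted as lower, was nearly equal by summed FPKM (68.1 against 71.3 FPKM). The list's median log2 fold was 0.00 (percentile 42.4), which was the value of Elane, at 0 FPKM in both populations. Of 16 measured T cell markers, 9 were under 1 FPKM in both populations, among them Cd3e at 0.415 FPKM in F4/80-negative cells and 0.399 FPKM in CD301b macrophages. Of 11 tested T cell markers, 2 were higher, Cd4 (3.78-fold, 18.6 FPKM) and Cd28 (3.78 against 0.924 FPKM), and Il7r was lower (9.40 against 16.8 FPKM), with the same counts when adjusted over the list alone. The T cell median log2 fold was -0.11 (percentile 28.45) and the mean 0.01, and the median became -0.36 with members at 1 FPKM or more. Among 7 tested natural killer cell markers, Klrd1 alone was past the threshold, also when adjusted over the list alone, with Ncr1 at 0.313 FPKM in F4/80-negative cells and 0.406 FPKM in CD301b macrophages. The natural killer cell median log2 fold was -0.18 (percentile 14). Of 10 B cell markers, 2 were tested: Cd79b was 3.07-fold higher in CD301b macrophages at 18.0 FPKM and Ebf1 was lower at 2.44 against 3.17 FPKM, also when adjusted over the list alone. The B cell median log2 fold was -0.02 (percentile 46.6) with a mean of 0.10, and the median became 0.60 with members at 1 FPKM or more. None of the 3 tested gamma delta T cell and innate lymphoid markers was past the threshold, 2 were lower when adjusted over the list alone, and the median log2 fold was -0.15 (percentile 4.73). Il1rl1, the most abundant of them, was 14.7 against 19.1 FPKM, and Sox13 was 0.831 against 1.08 FPKM.

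Markers of fibroblasts and keratinocytes were detected in both populations, and their called members were lower in CD301b macrophages. Of 14 fibroblast markers, 3 were lower in CD301b macrophages, none was higher and 11 were not past the threshold (5 lower and 1 higher when adjusted over the list alone), with a median log2 fold of -0.45 (percentile 0.02). Col1a1, the main chain of type I collagen, was 1676 FPKM in F4/80-negative cells and 1293 FPKM in CD301b macrophages and was not past the threshold. Dpt, Postn and Lum, matrix proteins of dermal fibroblasts, were 1.92-fold, 1.74-fold and 1.64-fold lower. Of 14 keratinocyte markers, 5 were lower and none was higher, also when adjusted over the list alone, with a median log2 fold of -0.37 (percentile 0.06), and Lgals7 (2.46-fold), Perp (2.18-fold), Krtdap (14.04 against 28.1 FPKM) and Sfn (1.91-fold) had the largest log2 folds among them. None of 12 endothelial markers was past the threshold, also when adjusted over the list alone, and their median log2 fold was -0.26, at percentile 0.56 of matched random lists and so outside their central 95%. Pecam1 was 26.9 and 26.7 FPKM in F4/80-negative cells and CD301b macrophages, and Plvap was 29.8 and 20.6 FPKM. Of 7 tested platelet and erythroid markers, Pf4 and Ppbp were 2.63-fold and 2.61-fold higher in CD301b macrophages and no other was past the threshold, also when adjusted over the list alone. Pf4 and Ppbp encode platelet chemokines, while the platelet integrin Itga2b was 0.512 against 0.929 FPKM and not past the threshold. The platelet and erythroid median log2 fold was 0.14, at percentile 96.2 of matched random lists, and became 0.83, at percentile 99.9, with members at 1 FPKM or more. In the list of muscle and adipocyte markers, Fabp4 was lower and 6 other tested genes were not past the threshold, also when adjusted over the list alone, with a median log2 fold of 0.31, of the opposite sign to Fabp4 and at percentile 99.96 of matched random lists.

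**Figure D3:**
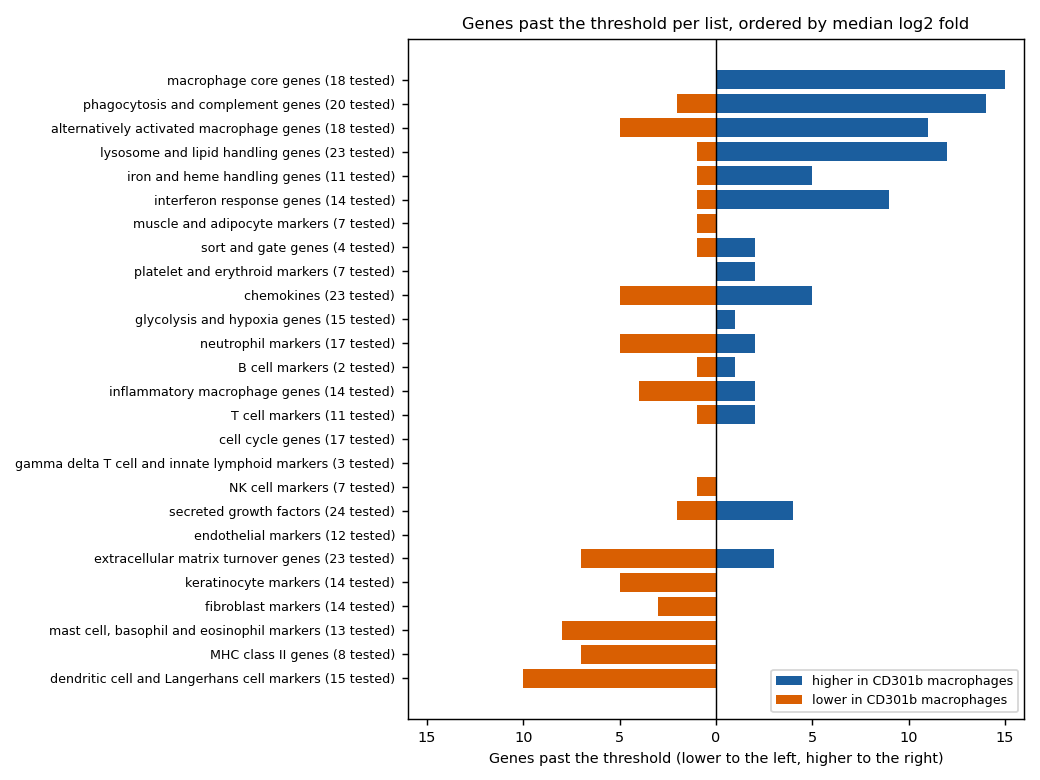
Number of genes past the threshold in each of the 26 lists, higher in CD301b macrophages to the right (blue) and lower to the left (orange), with the number of tested genes beside each list's name. Lists are ordered from the highest median log2 fold (macrophage core genes, 15 higher) to the lowest (dendritic and Langerhans cell markers, 10 lower).

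The values were given per transcript, so differences between the values listed for the transcripts of a gene could be read. How reads shared by several transcripts of a gene were divided among them is not given in the sources used here. Of 2649 genes with at least 2 tested transcripts, 13 had transcripts past the threshold in opposite directions. The most abundant was Clta, the clathrin light chain A, in which NM_001080386 was higher in CD301b macrophages (452 against 224 FPKM) and NM_001080384 was lower (39.7 against 115 FPKM). In Eif4a2, a translation initiation helicase, NM_013506 was higher (17.1 against 9.76 FPKM) and NM_001123038 was lower (8.87 against 24.3 FPKM). In Inpp5d, which encodes the phosphatase SHIP1, NM_010566 was higher (47.9 against 24.0 FPKM) and NM_001110192 was lower (8.35 against 15.7 FPKM). In Fyb, an adaptor of immune cells, NM_011815 was higher (66.0 against 30.5 FPKM) and NM_001278269 was lower (0.766 against 2.07 FPKM). In 17 genes the transcript that dominated, with at least 5 FPKM and at least 60% of the gene's FPKM in its population, differed between the populations. In 10 of them neither of the 2 transcripts was past the threshold in the authors' table, in 6 one of them was, and in Camk2g alone, named after its values were seen, both were. The switch itself was not tested, because its error cannot be computed from 1 value per population.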

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

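Coding transcripts alone, genes alone in their locus and a minimum gene fold were chosen after seeing the data. No paired analysis was possible because the table gives 1 value per population and none per library, and for the same reason the planned fits that leave out each replicate were not run. At an adjusted p of at most 0.01, calls went from 2408 to 1390 transcripts, from 2240 to 1309 genes and from 13 to 6 genes with opposite transcripts. With a log2 fold of at least 1 as well, 600 transcripts and 476 genes remained by construction. Bonferroni adjustment of the Cuffdiff p-values left 0 transcripts, since the lowest deposited p of 5e-05 cannot pass it over 16921 tests, while 4581 transcripts had an unadjusted p under 0.05. The other settings gave between 2008 and 2472 transcripts, between 1753 and 2322 genes and 11 genes with opposite transcripts, and the share of higher genes stayed between 60.3% and 68.3% over all settings that called any. Taking the dominant transcript alone called 2114 genes, of which 2103 were among the main 2240, and combining transcripts by Simes' method called 2322, of which 2151 were. Scaling each population to its median gene by a factor of 0.11 on the log2 scale moved the median fold from 0.08 to -0.01 and turned the sign of 5 of 2240 called genes, none of them named in the text by rule. It brought the share of the 11184 genes above 1 FPKM in both populations with a positive fold from 58.9% to 48.6%. None of the 590 recomputed folds of the 118 named genes reversed among those called, and 21 moved by over 1.5 times, 20 of them with a pseudocount of 10. A pseudocount cannot change the sign of a fold, and rescaling shifted folds by only about 0.11. The dominant transcript alone can change it only in genes with several transcripts. The absence of reversals was therefore largely fixed by these settings. Of 26 lists, 15 had a median outside the central 95% of random lists, against 16 with a pseudocount of 0.1, 15 with a pseudocount of 10, 15 with median scaling and 17 with members at 1 FPKM or more. The 3 list medians that moved out of the central range were those of platelet and erythroid markers under a pseudocount of 0.1 (0.30) and with members at 1 FPKM or more (0.83), and of T cell markers with members at 1 FPKM or more (-0.36). The B cell median, inside that range, went from -0.02 to 0.60 with members at 1 FPKM or more. The missing depth limits what can be said of genes near the tested minimum of 0.336 FPKM.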

Other observations

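The gene groups and tests in this part were chosen after the table was seen, except for the marker lists already described. Most Toll-like receptors and a chosen group of Fc receptor genes were higher in CD301b macrophages. Of 12 Toll-like receptors, 9 were higher and none was lower, with a median log2 fold of 1.04. The nucleic acid sensors Tlr7 and Tlr8 were 3.40-fold and 3.64-fold higher, Tlr1 was 3.37-fold higher, and Tlr2 (165 against 127 FPKM) was not past the threshold. All 7 genes of the chosen Fc receptor group were higher, with a median log2 fold of 1.28. Fcer1a and Fcer2a were left out of that group and had lower FPKM in CD301b macrophages. Fcer1a was not past the threshold, but was lower when adjusted over its marker list alone, and Fcer2a was not tested. Fcrls was 3.74-fold higher, Fcgrt, the neonatal Fc receptor, 3.17-fold, and Fcgr3 2.44-fold. Of 10 P2 purine receptors, 5 were higher and 1 was lower, with a median log2 fold of 0.64: P2ry12 was 4.43-fold higher (26.3 against 5.93 FPKM), P2ry13 3.79-fold higher and P2ry10 5.91-fold lower. Of 22 immediate early and heat shock genes, 5 were higher, 2 were lower and 15 were not past the threshold, with a median log2 fold of 0.15.

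Among genes associated with osteoclasts, the multinucleate cells that resorb bone, more were lower than higher in CD301b macrophages. Of 17, 9 were lower, 1 was higher, 6 were not past the threshold and 1 was not tested, with a median log2 fold of -0.75. Ctsk and Mmp9, both lower, also stand in the list of matrix turnover genes. Besides Ctsk, the acid phosphatase Acp5 was 3.11-fold lower (72.7 against 226 FPKM), the fusion gene Ocstamp 5.33-fold lower (1.70 against 9.05 FPKM) and the proton pump subunit Atp6v0d2 2.22-fold lower. The fusion gene Dcstamp, at 1.90 against 15.1 FPKM, was not past the threshold, and Tnfrsf11a, which encodes the receptor RANK, was 1.86-fold higher. Of 16 monocyte markers, 8 were lower and 1 was higher, with a median log2 fold of -0.59, among them S100a4 (2.08-fold lower), Plac8 (1.85-fold lower) and F10 (2.84-fold lower), while Ccr2 was 153 against 110 FPKM and not past the threshold. The 9 measured CD209 and CD301 lectins split: Cd209a, Cd209c, Cd209d, Cd209e and Mgl2 were lower, and Cd209b, Cd209f, Cd209g and Clec10a were higher. Of 15 host genes of small nucleolar RNAs, 8 were lower and none was higher, with a median log2 fold of -0.97. Snhg1 was 3.19-fold lower (43.5 against 139 FPKM) and Gas5 2.68-fold lower. Of 1091 tested noncoding transcripts, 62 (5.68%) were lower and 29 (2.66%) higher in CD301b macrophages, and of 15830 coding ones 807 (5.10%) were lower and 1510 (9.54%) higher. The difference between these shares was not tested.

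Mgl2, the gene of the lectin by which the macrophages were named, was 2.09-fold lower in the CD301b macrophage libraries, and swapped group labels are argued against by the macrophage core list, whose median log2 fold was 1.22 in favour of these libraries. Shared reads that average the folds of Mgl2 and Clec10a are argued against by their difference of 1.69 on the log2 scale. Shared reads given to Mgl2 in one population and to Clec10a in the other stay open. Of the 50-base words of Mgl2, 15.7% occur in Clec10a, and Mgl2 was 52.2% lower. Comparing these values cannot decide, because it assumes even coverage and leaves out reads of Clec10a given to Mgl2. The read length is not given in the sources used here, and the sum of both genes was 227 against 216 FPKM. Another candidate explanation is that the F4/80-negative gate held dendritic cells bearing CD301b: the dendritic and Langerhans cell list, which does not contain Mgl2, had a median log2 fold of -0.95. That test does not show that Mgl2 came from those cells, and a difference between transcript and surface protein in the macrophages was not tested.

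The F4/80-negative libraries held macrophage transcripts. Over the 13 macrophage core genes at 100 FPKM or more in CD301b macrophages, the level in F4/80-negative cells ranged from 27.1% (Adgre1) to 113% (Cd14) of the macrophage level, with a median of 43.0%. Whether these were macrophages with little F4/80 on the surface, free RNA from lysed macrophages, or other myeloid cells that express these genes was not tested.

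The lists of other cell types had different medians. Over members at 1 FPKM or more, the median log2 fold was -1.05 for dendritic, -0.98 for mast cell, basophil and eosinophil, -0.45 for fibroblast, -0.37 for keratinocyte and -0.26 for endothelial markers, -0.36 for T cell (7 genes), -0.30 for natural killer cell (5 genes), -0.27 for gamma delta T and innate lymphoid (2 genes), -0.05 for neutrophil (5 lower and 2 higher), 0.46 for muscle and adipocyte (5 genes), 0.60 for B cell (2 genes) and 0.83 for platelet and erythroid markers (6 genes). If their markers were absent from macrophages, a lower share of macrophages in the F4/80-negative libraries would raise every other cell type there alike. The first 5 of these medians spanned 0.79. Genes permuted among the 5 lists reached that range with p = 0.00635 (permutation test, 63 genes, 100000 permutations). That cannot decide against a lower macrophage share as the whole cause, because markers that macrophages also express would be raised less. Whether the markers were absent from these macrophages was not tested. These 5 lists and the test were also picked after the medians were seen, and genes are not independent replicates. An enrichment of dendritic and mast cells by the sort itself, and different amounts of carried-over skin cell RNA, may each contribute and were not separated.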
